A study of Daphnia magna with 12 samples.

How the data were processed

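Gene expression was measured in whole Daphnia magna, a freshwater crustacean widely used in ecotoxicology, with 2-colour Agilent microarrays. Per the labels' protocols, daphnids were kept for 96 h with ZnO nanoparticles, with the soluble salt ZnCl2 or with neither (blank), each metal at its EC10 for immobilisation, and the medium and the spike were renewed after 48 h. RNA of 40 pooled daphnids per replicate was extracted, and 100 ng was amplified and labelled. Each of the 12 arrays compared 1 exposure sample with a zinc reference, made per the design text from equal aliquots of the ZnO, ZnCl2 and blank samples. In each group of 4 replicates, 2 carried the exposure sample in Cy3 and 2 in Cy5, with the reference in the other dye. The design text also names copper exposures, which were not analysed here.

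The values are log2 ratios of exposure sample over reference, 1 per probe and array, as deposited by the authors in a table of 4318 probes and 12 arrays with no missing value. The submitters' processing notes name limma, without a version. Background correction, within-array normalization and the rule by which probes were kept are not given in the sources used here, and probe intensities were not used here, so neither the signal over background nor a probe filter on brightness could be applied. Column medians lay between -0.06 and 0.02 and column SDs between 0.32 and 0.62. On each array, 334 to 1370 values were shared exactly with another probe, and the cause of these ties is not given in the sources used here. Columns with the exposure sample in Cy3 carry at most 6 significant digits and the others up to 10.

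The table does not state the direction, centring or log base of its ratios, and these were checked first. The contrast of ZnO with blank in the Cy3 arrays correlated with that in the Cy5 arrays at 0.53 across probes, and the contrast of ZnCl2 with blank at 0.66. The contrast of ZnO with ZnCl2, for which no probe passed the threshold given below, had the opposite sign at -0.16. The mean over the groups correlated at -0.57, which is the sign change of a dye bias after turning. On the contrasts with blank and on this mean, the columns were taken as already turned to 1 direction. Because the reference is an equal mixture of the samples, unbiased ratios of a probe would average below 0 over the arrays. The expected amount is set by how much the arrays differ. Normalized ratios need not keep to this: DM00681P4 averaged 0.09 in the blanks, 0.29 in ZnCl2 and 0.20 in ZnO. Over all probes, observed means followed the expected amount with a slope of 0.97 for log2 of exposure over reference. It was 0.71 for the natural log, 0.37 for log10 and -0.69 for log2 of reference over exposure. Probes whose arrays differ most weigh most in this slope. The direction used throughout is exposure over reference on a log2 scale. The lowest correlation between arrays of 1 orientation was -0.32, for ZnO replicate 1 and blank replicate 2. The labels state the dyes, and an exposed and a blank sample can oppose each other against a mixture, so the direction was kept.

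The deposited ratios were tested in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, in 1 fit of all 12 arrays with a mean per group and a dye term per probe, which left 8 residual degrees of freedom. Contrasts between groups cancel the reference. The p-values are two-sided and Benjamini-Hochberg adjusted over the 4318 probes, with a threshold of 0.05, and intervals are 95% intervals from the same fit. The dye term passed the threshold for 1586 probes, with a median absolute size of 0.11. The replicates are separate pools from replicate exposures per the labels and the design text. Nothing says whether they came from separate cultures, so p-values measure only the spread between these pools, which may be technical. The number of arrays limits the precision: the median half-width of the interval for a difference between groups was 0.26 on the log2 scale. No array was identical to another. Same-numbered arrays of different groups did not vary together (1 of 12 pairs had a correlation of residuals over 0.1), so the replicate number names arrays and pairs none.

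The fit was tested on simulated data with the real probes' spread and dye terms and 200 changed probes. For ZnO against blank it recovered 47.8% of changes of 0.5, 79.1% of changes of 1 and 93.9% of changes of 2 on the log2 scale, and for ZnCl2 against blank 68.7%, 89.6% and 97.0%. False calls were 6 of 153 and 11 of 181. For ZnO against ZnCl2 it recovered 67.2%, 88.1% and 95.5%, with 6 false calls of 173. Each comparison was simulated in 1 draw with its own changed probes. The median half-width of the interval in the real data is 0.26 in each comparison, so the percentages do not show that their power differs.

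The groups, comparisons, tests, alternatives, gene lists and the rule for naming probes were fixed before the data were examined. None of the 4318 probe identifiers was found among the identifiers of the 28335 genes of the RefSeq table for the ASM2063170v1.1 assembly, and the files do not pair probes with genes. The gene lists fixed beforehand could therefore not be tested, and probes could not be averaged per gene. Under the rule for unnamed probes, the 2 with the largest rise and the 2 with the largest fall past the threshold are given per comparison. The arrays of the 2 groups compared did not overlap for any named probe, which was not a condition of the choice. For ZnO against ZnCl2, where no probe passed, the rule was read after the count was seen as the 2 higher and the 2 lower probes with the smallest p.

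The alternatives were no dye term, the replicate number as a block, only the 2 groups compared, only the arrays of 1 dye orientation, median centring, equal median absolute deviation, leaving out the 25% of probes with the smallest mean absolute ratio, a robust spread estimate, array weights, an adjusted p under 0.1, at least 1.5-fold change, the Cy3 ratios turned, and leaving out each array in turn. Added after seeing the data was the contrast of the mean of both zinc groups with blank, used to pick zinc-responsive probes without using the difference between ZnO and ZnCl2. Also added were leaving out the array with the largest residual SD of each group, leaving out the 5% of probes with the largest residual SD, and a covariate from those probes. Scores are means over the probes of a set after the fitted dye term was removed. They were compared with exact permutation tests. Chance correlation between the 2 comparisons with the same blanks was simulated in 100 draws of unchanged groups. Figures were drawn with matplotlib 3.10.9.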

Results

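The data comprise log2 ratios of 4318 probes in whole Daphnia magna after 96 h with ZnO nanoparticles, with ZnCl2 or with neither (blank), 4 pools of 40 daphnids each. Every pool was hybridised against a common zinc reference mixed from the 3 groups, so an unbiased ratio below 0 is a level under the average of the groups. The design asks how transcript levels change with the nanoparticle and with the salt, and whether nanoparticle and salt differ. Probes are identified by their array identifiers because the files do not pair them with genes.

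ZnO nanoparticles changed 384 probes (8.89% of those measured) against the blank, of which 249 rose and 135 fell. At least 2-fold changes numbered 50 rises and 28 falls, and 10 rose and 0 fell at least 4-fold. The median change was 0.64 among the rises and -0.63 among the falls on the log2 scale. The largest rise was that of probe DM02665P1, at 42.9-fold (95% interval 24.7 to 74.5; log2 change 5.42 ± 0.36 SE, limma adjusted p = 1.4e-05). Its ratio averaged -5.19 ± 0.54 (SD, n = 4) in the blanks and 0.24 ± 0.91 in ZnO. ZnO replicate 1 stood apart there, at -1.13 against 0.60 to 0.79 in the other ZnO arrays. Probe DM11283P1 rose 24.2-fold (interval 21.3 to 27.5, limma adjusted p = 2.2e-10), from -3.97 ± 0.10 in the blanks to 0.63 ± 0.14 in ZnO (SD, n = 4), the smallest p of the comparison. Blank signal over background is unknown, so the folds of both probes, here and with the salt, may depend on the background. The largest falls were smaller and less certain. DM02071P1 fell by 1.97 on the log2 scale (SE 0.54, limma adjusted p = 0.049) and DM01650P3 fell by 1.79 (SE 0.42, limma adjusted p = 0.027). DM02071P1 passed the threshold in 6 of its 25 alternative settings (adjusted p up to 1.00), and its call ended without any 1 of the 4 blanks, ZnO replicates 1, 3 or 4, or ZnCl2 replicates 3 or 4. DM01650P3 passed in 16 of 26, and its call ended without blank replicate 2 or 4 or ZnO replicate 1 or 4 (adjusted p 0.0666 to 0.0853).

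Of the 384 probes, 374 had ZnO and blank arrays that did not overlap once the dye term was removed. Over all probes, which were not chosen for separation, this share was 20.7%, against 2.86% by chance for 4 exchangeable arrays against 4. The dye term was fitted with the real groups, so its removal can raise the chance share above 2.86%. For ZnO against ZnCl2 the share was 4.24%. The count of 384 depends on single arrays. It was 206 without ZnO replicate 1 (55 falls), 225 without blank replicate 4 (59 falls) and 247 without blank replicate 1 (76 falls). It was 50 within the Cy3 arrays (2 against 2, 6 falls) and 38 within the Cy5 arrays (3 falls). Without the array of largest residual SD in each group it was 194 (59 falls).

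The zinc salt changed 389 probes (9.01%) against the blank, of which 288 rose and 101 fell. At least 2-fold changes numbered 63 rises and 12 falls, and 20 probes rose and 0 fell at least 4-fold. The median change was 0.65 among the rises and -0.56 among the falls. DM02665P1 again rose most, 64.4-fold (95% interval 37.1 to 112, log2 change 6.01 ± 0.36 SE, limma adjusted p = 5.0e-06), to 0.82 ± 0.24 (SD, n = 4) in ZnCl2. DM11283P1 rose 23.9-fold (interval 21.1 to 27.2, limma adjusted p = 2.3e-10), to 0.61 ± 0.16. DM07982P1 fell by 1.71 on the log2 scale (SE 0.22, limma adjusted p = 0.0010), from 0.61 ± 0.20 in the blanks to -1.10 ± 0.65 in ZnCl2. Its ratio was -2.07 on ZnCl2 replicate 4, against -0.91 to -0.64 on the other ZnCl2 arrays. Without that array the log2 change was -1.43. DM08755P3 fell by 1.67 (SE 0.43, limma adjusted p = 0.038) and passed the threshold in 12 of its 26 alternative settings. Its call ended without any 1 of the 4 blanks, ZnCl2 replicates 1, 2 or 3, or ZnO replicate 1 (adjusted p 0.0523 to 0.120).

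In the ZnCl2 comparison 385 of the 389 probes had arrays that did not overlap between the groups. Over all probes, which were not chosen for separation, this share was 19.6%, against 2.86% by chance, with the same limit on the chance share. The count was 234 without ZnCl2 replicate 3 (51 falls) and 239 without blank replicate 1 (54 falls). It was 88 within the Cy3 arrays (10 falls) and 64 within the Cy5 arrays (1 fall). Without the array of largest residual SD in each group it was 250 (53 falls).

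**Figure D1:**
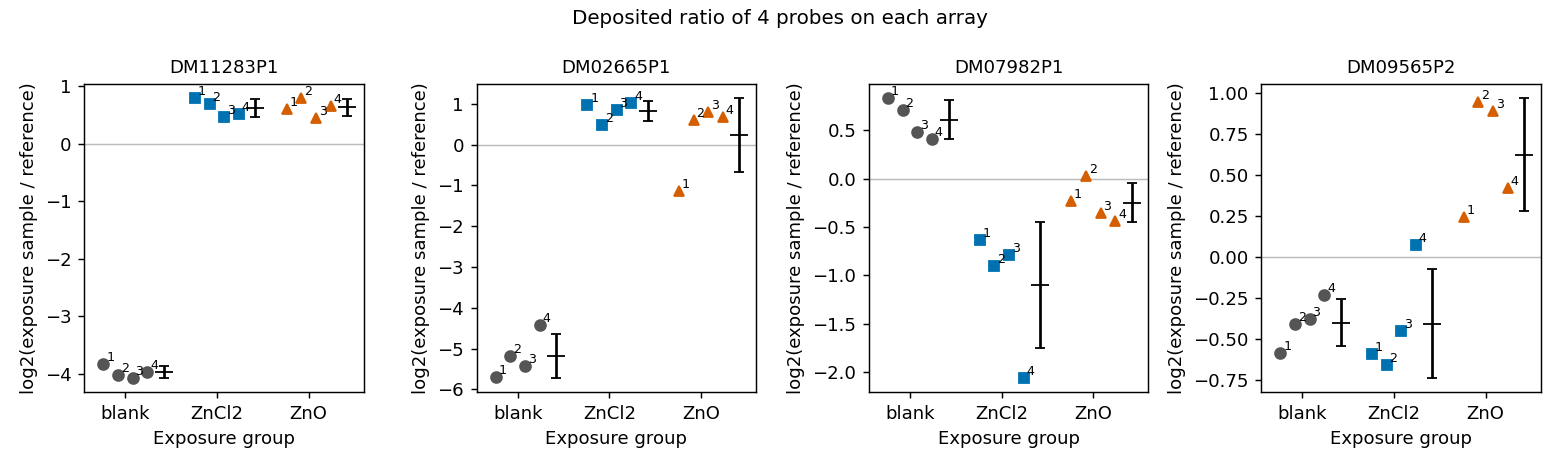
Deposited log2 ratio of exposure sample over zinc reference (vertical axis) by exposure group for 4 probes, with 1 point per array numbered by replicate and the mean ± SD of the 4 arrays in black. DM11283P1 and DM02665P1 lie near -4 and -5 in the blanks and above -1.2 on all 8 zinc arrays, DM07982P1 is lower in ZnCl2 than in the blanks, and DM09565P2 is higher in ZnO than in ZnCl2 without passing the adjusted threshold.

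Of the 384 probes called with the nanoparticle and the 389 called with the salt, 262 were shared. Both comparisons called 199 probes higher and 63 lower, and 0 probes were called in opposite directions. Independent lists of these sizes would share 16.6 higher and 3.16 lower probes, a figure that ignores the shared blanks. The highest of 100 simulated draws of unchanged groups that share the blanks had 1 probe past the threshold in both. Those draws hold no changed probe and vary each probe independently. Neither figure therefore tells how much of the overlap comes from the shared blanks. A further 249 probes passed in 1 comparison only. Of these, 245 had the same sign in the other comparison and 186 had an unadjusted p under 0.05 there. The shared blanks can raise both counts. Over all probes 77.7% had the same sign, against 66.6% in simulated unchanged groups that share the blanks. Of the 249, 58 had an unadjusted p under 0.05 for ZnO against ZnCl2, though passing in 1 comparison only favours such a difference. Across all probes, which are not independent replicates, the 2 responses correlated at 0.902 (Pearson) and 0.774 (Spearman). Leaving out single arrays gave a Pearson correlation of 0.818 (without ZnCl2 replicate 2) to 0.915. How much of it comes from the probes with the largest residual SD, described below, was not tested. Unchanged groups sharing the 4 blanks gave a simulated mean of 0.497 (Pearson) and 0.453 (Spearman). The covariance was 0.205, against 0.0303 simulated, a difference of 0.175. With a different pair of blanks for each response the Pearson correlation was 0.586 to 0.805 and the Spearman correlation 0.458 to 0.615.

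**Figure D2:**
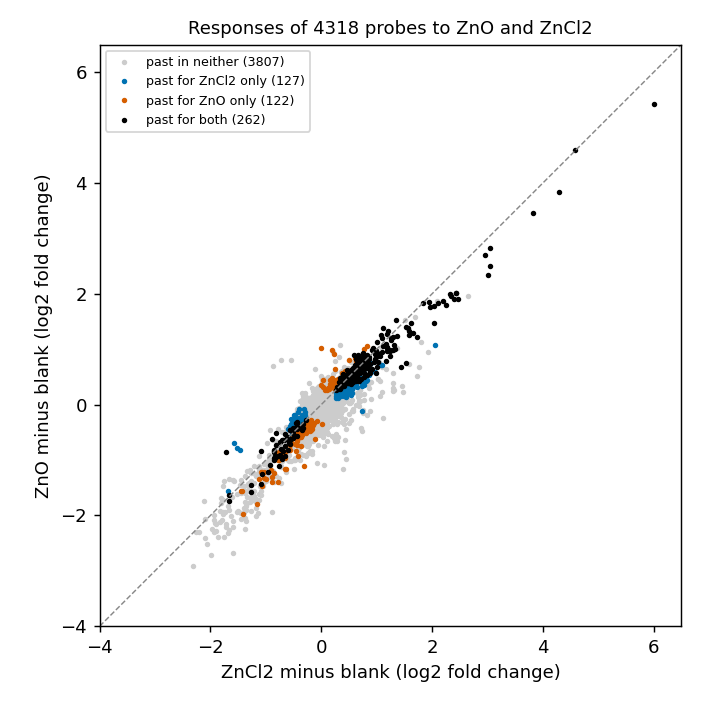
Log2 fold change of each of the 4318 probes in ZnO against blank (vertical axis) and in ZnCl2 against blank (horizontal axis), coloured by which comparison passed an adjusted p of 0.05, with the dashed line at equal change. The 262 probes past the threshold in both comparisons lie on the same side of 0 on both axes, and the farthest, DM02665P1, is at 6.01 for ZnCl2 and 5.42 for ZnO.

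Compared directly, ZnO and ZnCl2 differed at 0 probes in limma, with a smallest adjusted p of 0.35. At an unadjusted p under 0.05 there were 246 probes, where 215.9 would be expected with no difference. Across probes, the difference between ZnO and ZnCl2 in the Cy3 arrays correlated with that in the Cy5 arrays at -0.16. The 95% interval of the difference lay within 2-fold for 90.4% of probes and within 1.5-fold for 78.7%, so for the remainder a difference of that size was not excluded. The probes with the smallest p on either side did not pass the threshold. DM09565P2 had a ratio of 0.62 ± 0.35 (SD, n = 4) in ZnO and -0.41 ± 0.33 in ZnCl2, a difference of 1.03 (interval 0.64 to 1.43, limma adjusted p = 0.35). DM00226P3 was 0.35 higher in ZnO (interval 0.18 to 0.53, limma adjusted p = 0.71). DM09218P3 differed by -0.46 (interval -0.63 to -0.29, limma adjusted p = 0.35) and DM07384P3 by -0.79 (interval -1.14 to -0.43, limma adjusted p = 0.71). For DM11283P1 the difference was 0.02 (interval -0.17 to 0.20), and for DM02665P1 it was -0.59 (interval -1.38 to 0.21). DM07982P1 fell with the salt and also with ZnO (by 0.86 on the log2 scale, SE 0.22, limma adjusted p = 0.0406). ZnO lay 0.85 above ZnCl2 (interval 0.36 to 1.35), and this difference did not pass the adjusted threshold either (limma adjusted p = 0.71). The probe was named for its fall with the salt, which favours such a difference, and ZnCl2 replicate 4 lay lowest, at -2.07. ZnO and ZnCl2 were each used at their own EC10, and the concentrations were not used here.

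To compare nanoparticle and salt over the response as a whole, probes were picked on the mean of both zinc groups against blank, a choice made after seeing the data that does not use the difference between them. This gave 586 zinc-responsive probes, 365 that rose and 221 that fell. The count was 338 without blank replicate 1 and 330 without blank replicate 4, 172 within the Cy3 arrays (23 of them falls) and 72 within the Cy5 arrays (4 falls). The mean ratio of the rising probes was -0.55 ± 0.06 in the blanks, 0.22 ± 0.05 in ZnCl2 and 0.14 ± 0.08 in ZnO (SD, n = 4). The difference between ZnO and ZnCl2 was -0.08 (exact two-sided permutation p = 0.143, adjusted over the 2 scores 0.286), and it was -0.04 within the Cy3 arrays and -0.11 within the Cy5 arrays. The falling probes averaged 0.40 ± 0.10 in the blanks, -0.25 ± 0.14 in ZnCl2 and -0.33 ± 0.17 in ZnO, a difference of -0.08 (exact permutation p = 0.457, adjusted 0.457), with -0.02 within the Cy3 arrays and -0.13 within the Cy5 arrays. Tested among these 586 probes alone, 0 passed for ZnO against ZnCl2 (lowest limma adjusted p 0.27). An unadjusted limma p under 0.05 was found for 71, where 29.3 would be expected with no difference and p-values unaffected by the choice. The choice used the same residual SD of each probe, so 29.3 is not a sure baseline. Picked again in the same way for each of the 35 splits of the 8 zinc arrays into 4 and 4, the zinc-responsive probes held 11 to 216 with an unadjusted p under 0.05, and 12 splits, the real one included, gave at least 71.

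Array-to-array variation within groups was concentrated in few probes. The 5% of probes with the largest residual SD (216 probes, residual SD of at least 0.82 against a median of 0.17 over all probes) held 55% of the residual variance. Of these, 1 passed the limma threshold for ZnO against blank, DM02071P1 of the first set below, and 0 for ZnCl2 against blank. Outside the 216 lay 213 of the 221 falling and 363 of the 365 rising zinc-responsive probes, so a few belonged to both. Most of the 216 fell into 2 sets of probes that varied together. The first set (106 probes) averaged 0.57 ± 0.27 in the blanks, -0.78 ± 1.36 in ZnCl2 and -1.08 ± 1.10 in ZnO (SD, n = 4), with its lowest scores on ZnCl2 replicate 2 (-2.73), ZnO replicate 4 (-2.49) and ZnO replicate 1 (-1.39). Zinc and blank arrays differed by -1.50 on this score (exact two-sided permutation p = 0.030 for 8 arrays against 4, adjusted over the 2 sets 0.0606), by -1.63 within the Cy3 arrays and by -1.38 within the Cy5 arrays. With this score as a covariate in the fit, 57 of the 221 falling and 174 of the 365 rising zinc-responsive probes passed the threshold. All 221 and 365 kept their sign. The median change went from -0.55 to -0.44 among the falling probes (median SE 0.112 to 0.132) and from 0.56 to 0.50 among the rising ones (median SE 0.0996 to 0.124). The second set (87 probes) ranged from -2.20 on ZnO replicate 1 to 1.62 on blank replicate 2, and zinc and blank arrays differed by -0.07 (exact permutation p = 0.913), by -1.08 within the Cy3 arrays and by 0.94 within the Cy5 arrays.

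**Figure D3:**
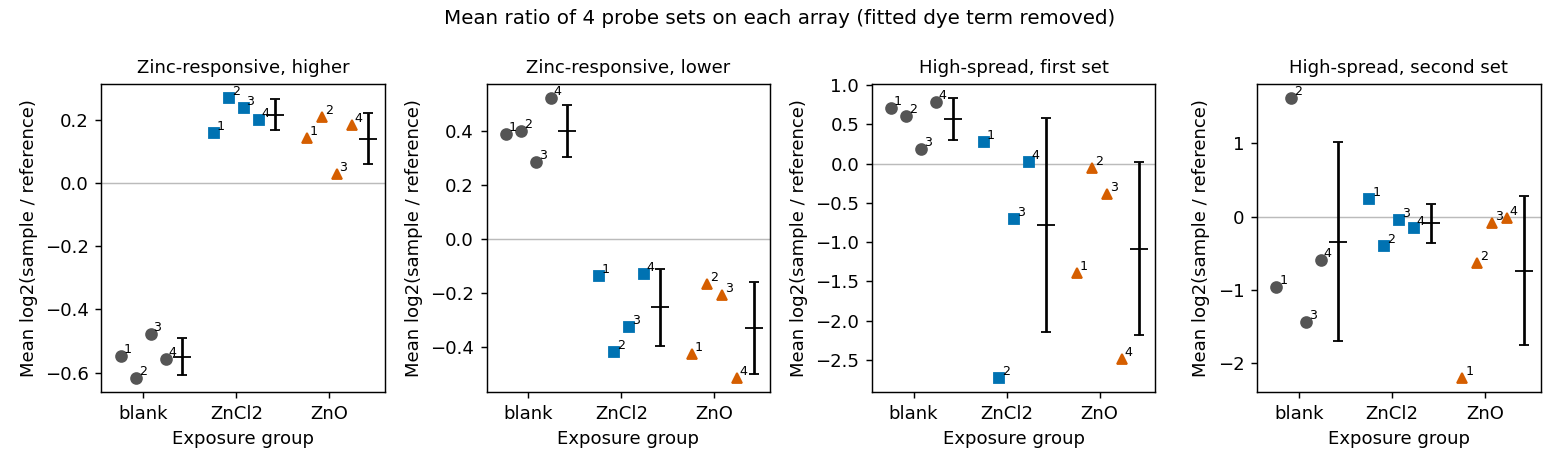
Mean log2 ratio of exposure sample over reference, dye term removed (vertical axis), by exposure group for 4 probe sets: zinc-responsive probes that rose (365) and fell (221), and the first (106) and second (87) sets of high-spread probes. Points are arrays numbered by replicate, with mean ± SD in black. The zinc-responsive sets, chosen for this difference, part the blanks from all 8 zinc arrays. The first high-spread set has an SD of 0.27 in the blanks and over 1 in both zinc groups, and the second an SD of 0.27 in ZnCl2 and over 1 in the other groups.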

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

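The tests in this part on other groupings of the arrays were planned for the comparisons with the blank, and those for ZnO against ZnCl2, for splits with balanced dyes and for the zinc-responsive probes were written after the results were seen. Among 48 groups of 4 values examined, 1 was picked out by the gap of its extreme array, fewer than the 2.4 that chance gives at about 1 in 20. On probe DM02665P1, ZnO replicate 1 had a ratio of -1.13 while the other 3 ZnO arrays lay between 0.60 and 0.79. Without that array the change against blank was 5.83 in place of 5.42.

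For ZnO against blank, 1 of the 35 splits of the 8 arrays into 4 and 4 gave as many probes as the real 384, the real one itself, and the highest of the others gave 25. For ZnCl2 against blank it was again 1 of 35, with 389 probes against at most 1 in the others. The share is under 0.05 for both, but splits that do not keep 2 arrays of each dye in each group have an SE of the difference 1.10 to 1.73 times as large at the same residual SD. Of the 18 splits that keep it, 1 gave as many probes in either comparison, with at most 25 and 1 in the others, and 18 splits are too few for a share under 0.05. For ZnO against ZnCl2 the real count was 0, which any of the 35 splits matches, so the splits decide nothing there; the highest of the others gave 9. The 71 zinc-responsive probes with an unadjusted p under 0.05 for ZnO against ZnCl2 were matched in 12 of the 35 splits (7 of the 18 balanced ones), with up to 216, so chance is not excluded for them.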

How the results depend on the processing

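ZnO against blank (384 probes) and ZnCl2 against blank (389) stayed within 1.5 times their count in 17 of 28 and 18 of 28 alternatives. The others, ZnO first, were 166 and 191 with no dye term, 50 and 88 in the Cy3 arrays alone, 38 and 64 in the Cy5 arrays alone, 698 and 588 at an adjusted p under 0.1, and 222 and 212 at 1.5-fold or more. Leaving out single arrays gave 206 to 489 and 234 to 432. Of settings added after seeing the data, leaving out the 3 arrays that stood apart gave 194 and 250, and the covariate from the first high-spread set 176 and 234. Turning the Cy3 ratios gave 0 and 0, since the table is already turned. It also put DM11283P1 at -0.031 for ZnO and -0.086 for ZnCl2, DM02665P1 at -0.15 for ZnCl2, DM01650P3 at 0.13, DM09565P2 at -0.19 and DM00226P3 at -0.093. The single-orientation counts rest on 2 arrays against 2; the cause of the other moves was not tested. The 586 zinc-responsive probes, picked after seeing the data, were 292 with no dye term, 172 and 72 in the Cy3 and the Cy5 arrays alone, 355 without the 3 arrays, 263 with the covariate, 895 at an adjusted p under 0.1, 276 at 1.5-fold or more, 0 with the Cy3 ratios turned and 330 to 640 without single arrays. ZnO against ZnCl2 gave 0 probes in all 29 alternatives. The correlation of responses was 0.807 in the Cy5 arrays, 0.805, 0.799, 0.744 and 0.586 with the blanks split 4 ways, and within its jackknife SE (0.0901) in the other 16 settings. With the replicate block the counts were 268, 285 and 0 in the order above. Same-numbered residuals correlated between -0.62 and 0.45, 1 of 12 arrays matched best with its own number, and no call was read from the block. Over 311 refits of the 12 named probe results, 260 kept direction and side of the threshold, 45 lost the call and 6 changed sign, all 6 with the Cy3 ratios turned. The 260 include the results for ZnO against ZnCl2, which had no call to lose (25, 25, 26 and 26 of 26 refits each). Among the called results, DM02665P1 and DM11283P1 kept their call in 25 of 26 refits in either comparison and DM07982P1 in 24 of 26. DM01650P3 kept it in 16 of 26, DM08755P3 in 12 of 26 and DM02071P1 in 6 of 25. Averaging probes per gene and the gene list tests were not run, as probes have no names here. What signal over background limits is unknown, because the table holds ratios only.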

Other observations

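The tests of noise of single probes, zinc exposure, shared variation and a shift of most probes in this part were chosen after the results were seen, while those with split blanks, with held-out arrays and of the lower probes with the covariate were set before their values were seen.

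The blank mean lay under -2 for 9 probes, the ZnO mean for 3, all 3 of them high-spread probes, and the ZnCl2 mean for 0. Because the reference is an equal mixture of the groups, a probe picked for a low blank ratio would, with unbiased ratios, be higher in at least 1 zinc group. No fold beyond the fitted one can be read from such probes, since blank signal over background is unknown.

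The first pattern is the close correlation of the ZnO and ZnCl2 responses. If variation of single blank arrays were its whole cause, the correlation would come near 0 once each response has its own blanks. The lowest value with the blanks split was 0.586. A deviation common to all the blanks would remain in either response after the split. The split therefore does not test such a deviation as the cause. A common response to zinc in both forms is a candidate explanation, and it was not tested against other stressors, because no exposure without zinc other than the blank is among the arrays.

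The second pattern is the high-spread probes, from which the fitted dye term was removed before they were picked, so their spread within an orientation bears on no dye effect, and an effect of dye beyond that term was not tested. Noise of single probes is argued against by 84.5% of their residual variance lying in 2 components. Shuffling the residuals of each probe separately within each group gave at most 33.4%. Arrays exchanged between blank and zinc are argued against because all 12 arrays scored on the side of their label when the rising probes were chosen without them. Zinc exposure stays open for the first set (adjusted exact permutation p = 0.0606) and for the second (0.913, which excludes nothing). A difference in the physiological state of the pools may underlie these sets, but no label records one and no biological explanation beyond the groups was tested.

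The third pattern concerns the 213 falling and 363 rising zinc-responsive probes that were not high-spread. The falling score and that of the first high-spread set, with no probe in common, were compared over the 8 zinc arrays. They correlated at 0.911 (Pearson, exact permutation p = 0.0016, adjusted over 2 relations 0.0032). The Spearman correlation was 0.905 (exact permutation p = 0.0046, adjusted 0.0091). Without ZnCl2 replicate 2 and ZnO replicate 4 the Pearson correlation was 0.963. The mean of the other probes also correlated with the set (0.944), as did 2879 of 10000 random lists of 213 of them at 0.911 or more. The slope on the set's score was 0.10 for the falling probes, 0.0227 for the other probes and -0.021 for the rising probes. A shift of equal size in most probes is therefore argued against as the cause. Among 10000 random lists matched on residual SD, 0 were as steep as the falling probes (median 0.037, highest 0.0679). Those lists were not picked for moving together, and they held no zinc-responsive probe. The falling probes were picked for being lower in zinc, and the first set's score was lower in zinc too. That choice may itself favour a steeper slope, so the 0 of 10000 is no independent support. A factor common to the array that acts more strongly on the falling probes is therefore not told apart. Variation shared by the falling probes and the first set is a candidate explanation, found and tested on the same arrays. The rising probes correlated with the set at -0.34 (permutation p = 0.42), and each dye orientation holds too few zinc arrays for a value of its own. With the first set's score as a covariate, 66 lower probes passed, 57 of them among the 221, whose median change went from -0.55 to -0.44 and median SE from 0.11 to 0.13. Whether the set may account for the falls stays open: all 221 kept their sign, and the rising probes, 174 of 365 still past, went from 0.56 to 0.50 with a median SE of 0.0996 before and 0.124 after.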
